A study of Homo sapiens with 6 samples.

How the data were processed

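Total RNA from human dermal fibroblasts was treated with DNase and made into poly(A)-selected mRNA libraries, per the labels' protocols. The 6 libraries fall into 2 groups of 3 by their titles, Ad-SOX9 and Ad-eGFP, and there is 1 comparison between them. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

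The deposited count table gives whole-number read counts per gene symbol, without normalization. Reads were assigned on genome build hg19 and compared with DESeq, per the submitters' processing notes, which give no version. The aligner, the counting program, its strand setting and the gene annotation are not given in the sources used here. The authors' deposited results table gives a mean signal per gene, which equals the mean of the counts divided by median-of-ratios size factors. It also gives the log2 fold change and its standard error as fitted by the authors, and the authors' p-values, unadjusted and adjusted. Genes marked as low have no adjusted p, and genes marked as outliers have neither. These tables name no positions and the reference used here is another build, so no coordinates are given.

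The count table has 23710 rows, of which 18683 had a count in some library. Of these rows 28 carry symbols that a spreadsheet turned into dates. They were kept in library sizes and tests (20 were tested and 9 called) but could not be named. Replicates of a group differed by more than sampling noise. Over the 6 pairs chi-square per degree of freedom was 2.07 to 3.67 for tested genes and 1.1 to 1.19 for those of low count. Repeated libraries of a single culture can also exceed sampling noise, so these values do not show that the cultures were separate. Each library was counted as a replicate. No column was left out among those that hold values per library. Genes that would show a person's sex are not reported.

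Counts were filtered with filterByExpr at its default minimum of 10 counts and a total of 15, which left 13488 genes. They were scaled by TMM and tested with the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the group as the only term. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with 0.05 as the threshold. The biological coefficient of variation was 3.87%. The same fit was tested against a fold of 1.5 with glmTreat. An SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic, and is approximate. CPM values use the TMM-scaled library sizes. A floor of 3 counts corresponds to 0.137 to 0.199 CPM in a library, and such floors and the counting intervals (95%, exact binomial) cover counting error only.

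The 31 gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The genes named are SOX9, the 10 genes with the highest and the 10 with the lowest fold among those called, without overlap between groups and with at least 5 CPM in the higher group, leaving out clone, pseudogene and antisense names, and up to 4 called members of each list with the largest change, or up to 2 of the highest level where fewer than 2 were called. Members beyond these are named to complete a count, except COL10A1 and HSP90B1, which were not called and are named outside this rule. Some genes that this rule picked are not reported here. Lists were tested with camera on voom values (limma 3.58.1) with a preset inter-gene correlation of 0.01, then with a correlation estimated per list, and with fry. One list, of mitochondrially encoded genes, had no row in the table, which left 30 tested. Camera asks whether a list moved more than other genes. The directional p of fry asks whether a list's genes move on balance one way, its mixed p whether they change in either direction, and neither compares the list with other genes. Camera called 9 lists at an adjusted p under 0.05, 4 higher and 5 lower. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, while fry called 20 by direction.

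Before use, the tests were run on simulated counts for the 13488 genes with the means and library sizes of this comparison and 50 genes changed at each fold. The edgeR test recovered 68% of genes changed 1.25-fold, 70% at 1.5-fold, 96% at 2-fold and 96% at 4-fold. It made 194 calls in all, of which 16 were among the 13263 unchanged genes. The simulated genes varied independently and far fewer changed than were called in the data, so these rates need not hold there.

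Alternatives were RLE, upper-quartile and library-size scaling, scaling without the SOX9 row, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 samples, an adjusted p under 0.01, the replicate number as a block, each library left out, and a loess correction for transcript length and GC content with and without the block. Length and GC content were taken by gene symbol for 97% of tested genes from a later human annotation, used for these properties alone. Leaving out the 2 libraries highest in interferon genes was chosen after seeing the data, as was applying the alternatives to the overlap with the authors' calls. SOX9 counts may hold reads of both the viral cDNA and the cell's own gene, which gene-level counts do not separate. Virus and eGFP reads were not analysed here.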

Results

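Gene expression was measured by RNA sequencing in human dermal fibroblasts, the collagen-producing cells of skin, infected with an adenovirus that carried SOX9 or, as the control, an adenovirus that carried enhanced green fluorescent protein (eGFP). Both viruses were used at a multiplicity of infection of 50, and RNA was taken on day 2. There were 2 groups of 3 libraries, called Ad-SOX9 and Ad-eGFP. The Ad-eGFP libraries held 17556130, 15167136 and 18227191 counts, and the Ad-SOX9 libraries 17832318, 21830906 and 17137503. SOX9 is the transcription factor that directs cartilage formation. The series studies its control of genes in chondrocytes, and the fibroblast comparison asks which genes respond when SOX9 is supplied to a cell that is not a chondrocyte. Levels are CPM, read counts scaled to a fixed library total, given as mean ± SD over 3 libraries unless stated, and folds are Ad-SOX9 over Ad-eGFP from edgeR's quasi-likelihood fit.

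SOX9 itself rose from 12.3 ± 0.288 CPM (SD, n = 3) in Ad-eGFP to 1733 ± 173 CPM in Ad-SOX9, a fold of 141 (log2 7.14, SE 0.11, adjusted p = 1.36e-07). Its counts were 216, 181 and 221 in the Ad-eGFP libraries and 34705, 37199 and 27694 in the Ad-SOX9 libraries, so each library matched its label. Of 13488 genes tested, 4709 (34.9%) changed, 2349 upward and 2360 downward. The split was 2896 and 1662 with library size as the only scaling, 2190 and 2612 with upper-quartile scaling and 2007 and 2642 with the length and GC correction. Most changes were small: the median absolute log2 change of the called genes was 0.26, while 288 genes were over 2-fold higher and 28 over 2-fold lower. Against a minimum fold of 1.5, 286 genes passed, 264 of them higher in Ad-SOX9 (171 and 162 by DESeq2). The lowest Ad-SOX9 value lay above the highest Ad-eGFP value, or the reverse, for 6121 genes (45.4%), where chance gives 10%.

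**Figure D1:**
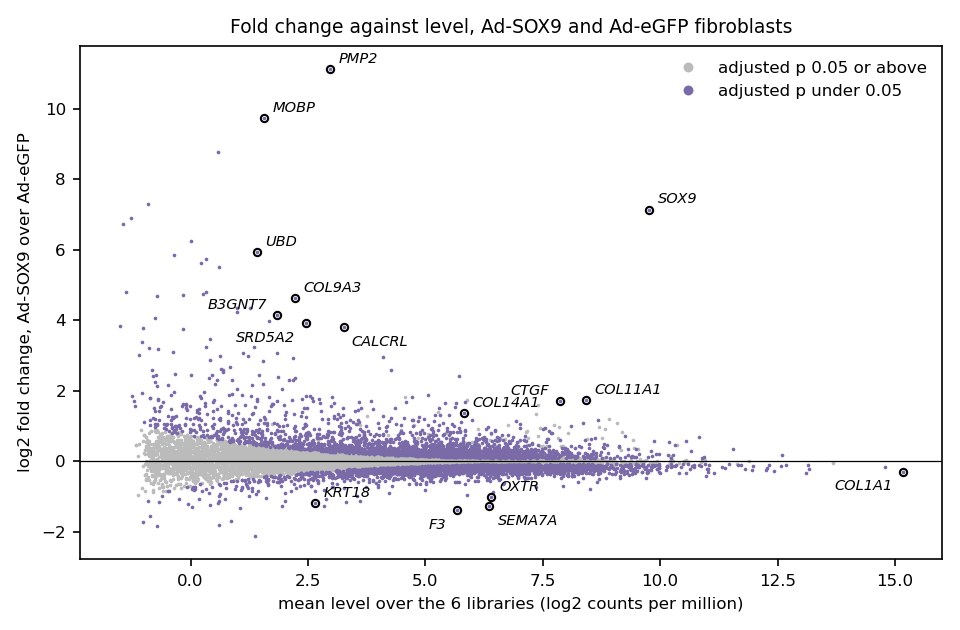
Each point is a gene, with its mean level over the 6 libraries on the x axis (log2 CPM) and its log2 fold change on the y axis; purple points have an adjusted p under 0.05. Apart from SOX9 at 7.14, the labelled genes that rose most, such as UBD and CALCRL (3.80), were of low level. The heights of PMP2 and MOBP rest on no control reads, so they are fitted values and not measured folds. The falls were smaller, with F3 at -1.38.

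The largest rises were of genes that were silent or nearly silent in the control. PMP2, a fatty acid binding protein of peripheral myelin, had 0 counts in Ad-eGFP and 892 in Ad-SOX9 (15.6 ± 1.51 CPM), and MOBP, a protein of oligodendrocyte myelin, had 0 and 340 (5.91 ± 0.668 CPM). Set against a floor of 3 counts over the Ad-eGFP group, PMP2 was at least 260-fold and MOBP at least 99.0-fold higher. UBD, a ubiquitin-like modifier, had 4 and 301 counts and rose 60.6-fold to 5.25 ± 0.771 CPM. The fold of UBD is uncertain for want of control reads, and its log2 value ran from 5.715 to 6.281 without 1 library each. B3GNT7, a glycosyltransferase of keratan sulfate synthesis, had 19 counts over the Ad-eGFP group and rose 17.8-fold. SRD5A2, the reductase that makes dihydrotestosterone, rose 15.1-fold. CALCRL, the receptor of calcitonin gene-related peptide and adrenomedullin, rose 13.9-fold to 17.9 ± 2.03 CPM. The adjusted p of these genes ran from 1.86e-20 for PMP2 to 1.92e-15 for UBD. Reads of PMP2 are uncertain to the extent that counting could split them with related fatty acid binding protein genes.

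The largest falls were near 2-fold. F3, the tissue factor that starts coagulation, fell from 73.8 ± 2.60 to 28.4 ± 1.44 CPM, 2.61-fold lower (adjusted p = 2.83e-20), and SEMA7A, a membrane-anchored semaphorin, from 116 ± 7.89 to 48.0 ± 1.64 CPM, 2.43-fold lower. OXTR, the oxytocin receptor, fell from 113 ± 3.30 to 55.6 ± 4.41 CPM. DUSP5, a phosphatase that switches off ERK, was 2.20-fold lower, and KCNQ5, a potassium channel subunit, 2.21-fold lower. FTCD of histidine breakdown, CPA4, a carboxypeptidase, and TDO2 of tryptophan breakdown were 2.42-, 2.40- and 2.09-fold lower. The keratins KRT18 and KRT34 were 2.27- and 2.18-fold lower, and reads of KRT18 could be shared with its pseudogenes.

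**Figure D2:**
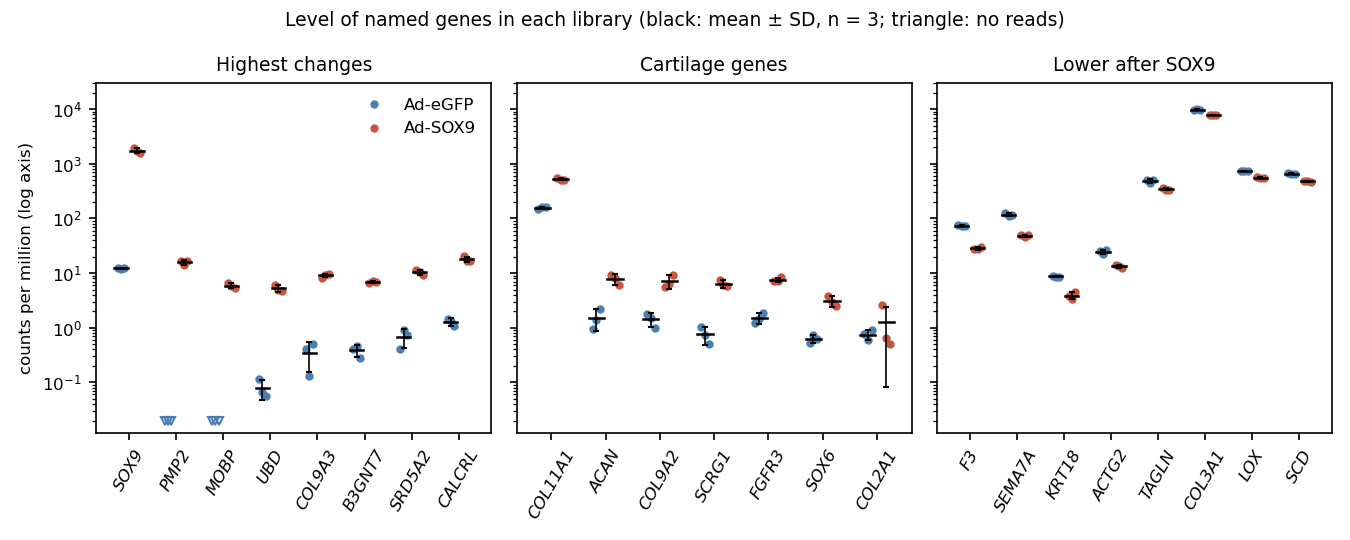
CPM of named genes in each of the 6 libraries on a log axis, with Ad-eGFP in blue and Ad-SOX9 in red; black lines are the mean ± SD of 3 libraries and open triangles mark libraries with no reads. PMP2 and MOBP had no reads in Ad-eGFP, COL11A1 rose to 526 CPM, and COL2A1 stayed near 1 CPM, with 1 Ad-SOX9 library at 2.60.

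Most cartilage matrix genes that passed the filter rose. Of 26 listed members, 13 passed it, and the others were too low to be tested. Of the 13 measured members, 9 rose and 1, COMP, fell (9 and 1 adjusted over the list alone), and the median log2 change was 0.69. With no filter 24 were tested, and again 9 rose and 1 fell. Without Ad-SOX9 replicate 1, 6 of 14 rose and the median was 0.404, and by DESeq2 6 rose. COL9A3 and COL9A2, chains of the type IX collagen that coats cartilage fibrils, rose 24.8-fold to 9.02 ± 0.679 CPM and 4.89-fold to 7.09 ± 1.94 CPM. In the Ad-eGFP group COL9A3 had 18 counts in all. ACAN, which encodes aggrecan, rose 5.11-fold to 7.82 ± 1.68 CPM (adjusted p = 2.27e-05), and SCRG1, a secreted protein of forming cartilage, 8.42-fold to 6.44 ± 1.0 CPM. Apart from SOX9, COL11A1 was the cartilage gene of highest level, rising 3.34-fold from 158 ± 6.41 to 526 ± 27.8 CPM (log2 1.74, SE 0.04). COL2A1, the main cartilage collagen and a known SOX9 target, did not pass: it was at 0.748 ± 0.148 CPM in Ad-eGFP and 2.60, 0.640 and 0.513 CPM in the 3 Ad-SOX9 libraries (adjusted p = 0.59), and its log2 change went from 0.69 to -0.37 without Ad-SOX9 replicate 1. COL11A1 and COL2A1 were chosen after their values were seen. The cartilage list was called higher by camera (adjusted p = 0.000121), but not with a correlation estimated from the data (adjusted p = 0.338 with an estimated correlation).

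Chondrocyte regulators moved both ways, with 5 of 18 higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.469). SOX6, a partner of SOX9 in chondrocytes, rose 4.95-fold to 3.08 ± 0.723 CPM, FGFR3, a receptor of growth plate chondrocytes, 4.94-fold to 7.61 ± 0.618 CPM, and PTHLH, the parathyroid hormone-like signal, 1.88-fold. GLI1 and PTCH1, targets of hedgehog signalling, and NOG, a secreted inhibitor of bone morphogenetic proteins, were among the genes that fell. The number that fell was 3 without Ad-eGFP replicate 2, Ad-eGFP replicate 3 or Ad-SOX9 replicate 1, and the call of NOG (log2 -0.75) ended without Ad-eGFP replicate 2 or Ad-SOX9 replicate 3. Of 10 hypertrophy and bone genes 4 rose, among them SPP1, which encodes osteopontin, 3.12-fold, MEF2C 2.18-fold, and RUNX2 1.3-fold. COL10A1, the collagen of hypertrophic chondrocytes, stayed low at a log2 change of -0.19 (adjusted p = 0.722), and the list was not called (camera adjusted p = 0.569; 4 higher and 3 lower adjusted over the list alone). VEGFA fell, and so did BMP4, whose call ended without Ad-eGFP replicate 1, Ad-eGFP replicate 2, Ad-SOX9 replicate 2 or Ad-SOX9 replicate 3. The list's falls then numbered 1, or 0 in the last of these fits. Of 24 genes of sulfated glycosaminoglycan synthesis, 7 rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.268), led by CHST11, the chondroitin sulfotransferase, at 1.86-fold and CSGALNACT2 at 1.39-fold. The 5 falls were 3 without Ad-eGFP replicate 1 or 3 and 2 without Ad-SOX9 replicate 1 or 2, and with library size as the only scaling 8 rose and 1 fell.

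Genes of the fibroblast matrix fell by small amounts. Of 29 measured, 20 fell and 2 rose (21 and 2 adjusted over the list alone), with a median log2 change of -0.13. COL1A1 went from 40578 ± 1069 to 33015 ± 1168 CPM (log2 -0.30, SE 0.03, adjusted p = 8.33e-11) and COL3A1 from 9749 ± 102 to 7784 ± 142 CPM, both chosen after their values were seen. LOX, which crosslinks collagen, was 1.32-fold lower and POSTN, which encodes periostin, 1.27-fold lower. COL14A1, a collagen associated with fibrils, went the other way, rising 2.57-fold from 32.0 ± 1.97 to 82.1 ± 1.53 CPM. The other rise, of FBLN5 (log2 0.09), did not pass without Ad-eGFP replicate 2, Ad-eGFP replicate 3, Ad-SOX9 replicate 1 or Ad-SOX9 replicate 2, and the count was then 1. The list was called lower by camera (adjusted p = 5.96e-07; adjusted p = 0.338 with an estimated correlation).

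Contractile genes, which mark myofibroblasts, fell with the matrix genes: 12 of 19 fell and 2 rose (13 and 2 adjusted over the list alone), with a median log2 change of -0.22. ACTG2 was 1.85-fold, TAGLN 1.41-fold and ACTA2, which encodes smooth muscle actin, 1.40-fold lower, and MYOCD, a coactivator of smooth muscle genes, was 1.51-fold lower. SYNPO2 and PALLD rose, and the count of rises was 1 without Ad-eGFP replicate 1 or Ad-SOX9 replicate 1. Camera called the list lower (adjusted p = 5.21e-05; adjusted p = 0.379 with an estimated correlation). Among 19 surface and lineage genes of fibroblasts, 12 fell and 3 rose (13 and 3 adjusted over the list alone). PDGFRB was 1.18-fold lower and S100A4, a calcium-binding protein, fell by 0.33 on the log2 scale, while PDGFRA was 1.16-fold higher. That list was called lower (adjusted p = 0.0198; adjusted p = 0.552 with an estimated correlation), and the call ended without Ad-SOX9 replicate 1 (adjusted p = 0.0505). Of 24 matrix proteases and inhibitors 6 rose and 9 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.369). The aggrecan-cleaving ADAMTS4 rose 2.08-fold and MMP11 1.94-fold, whereas PLAU, the urokinase, was 1.84-fold and MMP12 1.62-fold lower.

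**Figure D3:**
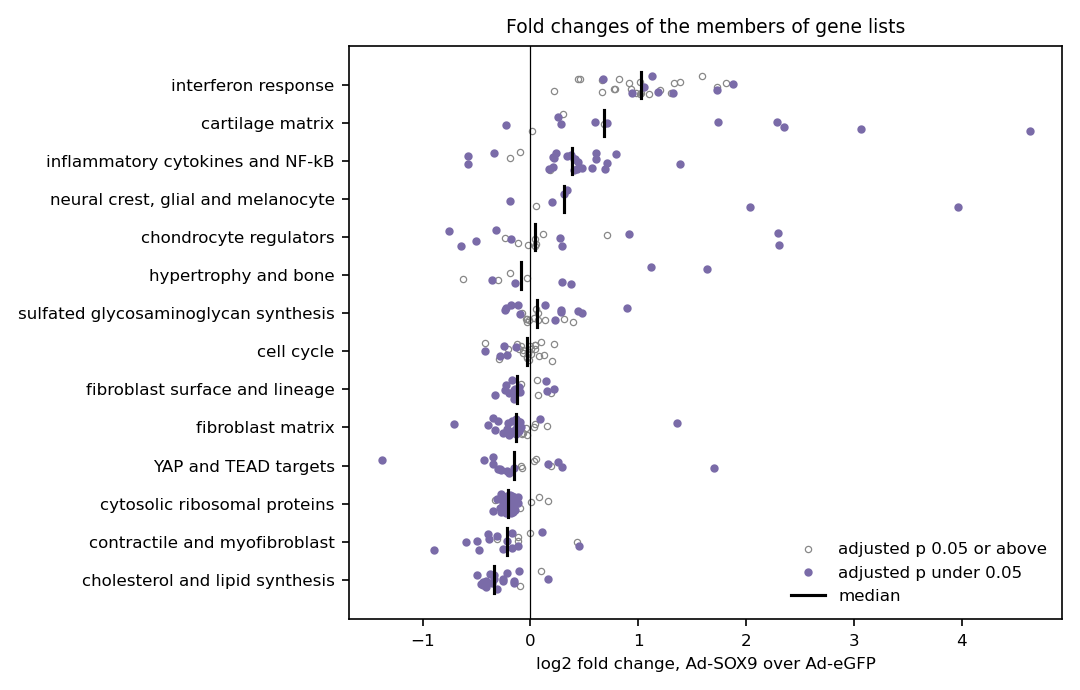
Log2 fold changes of the measured members of gene lists; filled points have an adjusted p under 0.05 over all genes, open points do not, and the black bar is the median. Interferon response members were all above 0 with a median of 1.03, and cytosolic ribosomal proteins lay in a narrow band around -0.21.

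Interferon response genes were higher in Ad-SOX9, and they also varied between libraries of the same group. All 30 measured members had a positive fold change (median log2 1.03), and 8 rose by the test (7 adjusted over the list alone), among them ISG20 at 3.32-fold, IFI27 at 2.49-fold and the chemokine gene CXCL11 at 2.27-fold. The mean log2 level of the 30 genes, relative to all libraries, was -0.02, -0.91 and -0.72 in the Ad-eGFP libraries and 0.37, 0.89 and 0.38 in the Ad-SOX9 libraries. The difference of 1.10 gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The number that rose was 17 without Ad-eGFP replicate 1, 3 without Ad-eGFP replicate 2, 4 without Ad-eGFP replicate 3, and 3, 4 and 3 without Ad-SOX9 replicates 1, 2 and 3, and it was 21 by DESeq2 and 3 with the replicate number as a block. Without both Ad-eGFP replicate 1 and Ad-SOX9 replicate 2, the highest of each group, it was 30. That choice was made after the data were seen and narrows the spread by construction. Camera called the list higher (adjusted p = 9.6e-16; adjusted p = 0.44 with an estimated correlation).

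**Figure D4:**
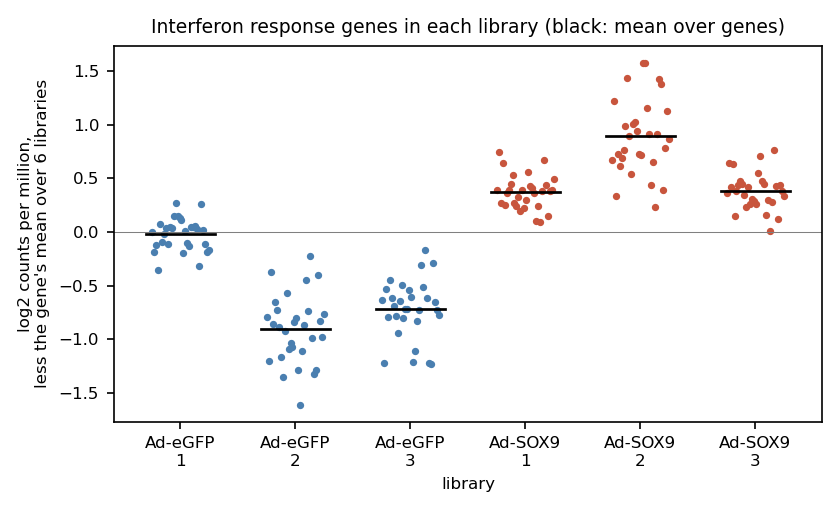
Each point is 1 of 30 interferon response genes in 1 library, as log2 CPM less the gene's mean over the 6 libraries; black bars are means over genes. The means were -0.02, -0.91 and -0.72 in Ad-eGFP (blue) and 0.37, 0.89 and 0.38 in Ad-SOX9 (red).

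Inflammatory cytokine and NF-kB target genes were also higher. Of 26 measured, 20 rose and 3 fell (20 and 3 adjusted over the list alone), with a median log2 change of 0.39. VCAM1, an adhesion molecule for leukocytes, rose 2.63-fold from 2.90 ± 0.255 to 7.54 ± 0.869 CPM, CCL5 1.73-fold, LIF 1.64-fold and BIRC3, an inhibitor of apoptosis, 1.62-fold. The falls were of PTGS2, IL33 and CCL7, and 1 of them was left without Ad-eGFP replicate 1 or Ad-SOX9 replicate 1. Camera called the list higher (adjusted p = 5.64e-08; adjusted p = 0.338 with an estimated correlation). Without the libraries highest in interferon genes, Ad-eGFP replicate 1 and Ad-SOX9 replicate 2, 20 were higher and 2 lower.

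Sterol and fatty acid synthesis fell: 18 of 21 genes fell and 1 rose (19 and 1 adjusted over the list alone), with a median log2 change of -0.34. SCD, the stearoyl-CoA desaturase, fell from 653 ± 14.1 to 474 ± 1.65 CPM, 1.38-fold lower (adjusted p = 1.37e-13), and INSIG1, which restrains sterol synthesis and is itself raised by its regulator SREBP, was 1.41-fold lower. DHCR7 and MVD, enzymes of cholesterol synthesis, were each 1.35-fold lower. The list was called lower by camera (adjusted p = 1.81e-10; adjusted p = 0.338 with an estimated correlation). Of 76 cytosolic ribosomal protein genes 69 fell (71 lower and 1 higher adjusted over the list alone), all by small amounts, with a median log2 change of -0.21. RPS21 was 1.28-fold lower. Camera called this list lower too (adjusted p = 1.82e-24; adjusted p = 0.36 with an estimated correlation), and 65 to 70 members fell under each of the scalings tried. Reads of these genes could be shared with their many pseudogenes.

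Cell cycle genes showed little change. Of 30 measured, 5 fell (1 adjusted over the list alone; camera adjusted p = 0.197), of which MCM6, a subunit of the replicative helicase, was 1.34-fold lower in a call held without each library. The number that fell was 1 without Ad-eGFP replicate 1 or Ad-SOX9 replicate 1, 3 without Ad-eGFP replicate 3 or Ad-SOX9 replicate 2, and 7 without Ad-SOX9 replicate 3, where the list was called lower (adjusted p = 0.00156). Among 19 targets of YAP and TEAD, 10 fell and 4 rose (11 and 4 adjusted over the list alone). CTGF, a secreted matrix protein, rose 3.24-fold from 110 ± 3.53 to 356 ± 29.1 CPM, while F3, FJX1 and AMOTL1 fell. The list was not called (camera adjusted p = 0.0584), although it was without Ad-eGFP replicate 1 (adjusted p = 0.0458) or Ad-SOX9 replicate 2 (adjusted p = 0.0361) and with no filter (adjusted p = 0.0293). TGF-beta response genes were divided, with 5 of 18 higher and 5 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.721). INHBA was 1.42-fold lower, and TGFB3 rose 1.48-fold and ID3 1.34-fold.

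Markers of other cell types that a skin culture could hold were mostly few and low. Of 7 measured genes of neural crest, glia and melanocytes, 5 rose and 1 fell (5 and 1 adjusted over the list alone). The melanocyte regulator MITF rose 1.24-fold. Camera called the list higher (adjusted p = 0.0476; adjusted p = 0.379 with an estimated correlation), but not with library size as the only scaling (adjusted p = 0.0603) or with the replicate number as a block (adjusted p = 0.0551). Of 4 endothelial genes KDR, a receptor of vascular endothelial growth factor, rose 6.42-fold to 3.08 ± 0.596 CPM and FLT1 was 1.22-fold lower (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.387). The other rise, of TEK (log2 0.91), was lost without Ad-eGFP replicate 2 or 3 or Ad-SOX9 replicate 1 or 3. Of 9 keratinocyte and hair follicle genes 1 rose and 5 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.134), with DSP, which encodes desmoplakin, 1.68-fold higher. Of 9 tendon and joint genes 2 rose and 3 fell, also as adjusted over the list alone (camera adjusted p = 0.451), among them THBS4, 2.27-fold higher at 1.55 ± 0.0518 CPM, and TNXB, 1.29-fold lower. Of 5 adipocyte genes PPARG fell, by 1.41-fold (1 lower adjusted over the list alone; camera adjusted p = 0.197), and without Ad-eGFP replicate 3 so did a further gene, CD36. The leukocyte markers CD68, at 122 ± 11.8 and 130 ± 8.87 CPM, and CD14, below 1 CPM in both groups, did not pass (adjusted p = 0.474 and 0.625; camera adjusted p = 0.631).

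The authors' deposited table of the same comparison lists 4199 genes at an adjusted p under 0.05, 2004 higher and 2195 lower in Ad-SOX9. Of the 13468 genes tested here that it lists, 4130 were called in both, all 4130 in the same direction, while 570 were called here only, 82 of them without an adjusted p in that table, and 69 in that table only. The log2 fold changes had a Pearson correlation of 0.948 across these genes, which are not independent replicates, and the slope of the authors' values on those here was 0.703. The gap was not even across genes. For PMP2 and UBD, of few or no control reads, the authors' log2 values were 5.10 and 3.57 against 11.1 and 5.92 here. For the abundant COL11A1 the values were 1.72 and 1.74. The authors' deposited table marks 212 genes as outliers with no p-value, among them SOX9 (log2 6.94) and CTGF (log2 1.67). Of those 212 genes, 61 were called here, 46 higher and 15 lower. Both analyses start from the same counts, so the overlap is not independent evidence.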

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

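The count of changed genes (4709), the rise of SOX9 and the overlap with the authors' calls (4130) kept within 1.5 times under each alternative run, at 3295 to 4867 genes, a log2 change of 7.06 to 7.2, and 3006 to 4133 shared calls. Without 1 library each, 3910 to 4432 genes changed and 256 to 297 passed at 1.5-fold. DESeq2 gave 171 genes at 1.5-fold (162 higher, 9 lower) where edgeR gave 286, and the cause was not tested. The 9 lists called by camera became 0 with an estimated correlation, 20 by fry's direction and 27 by its mixed test, which ask other questions. Under the other settings 7 to 11 lists were called. The replicate number as a block gave 4153 genes, 267 at 1.5-fold, and 4089 with the length and GC correction. Libraries of the same number had correlated deviations of -0.087, -0.083 and -0.079, and 0 of 6 libraries correlated best with their own number. No pairing by number was thus detected, but 3 libraries per group are too few to exclude it. The SOX9 row, left out of scaling, moved no call and tests nothing. Of 120 called genes picked by the naming rule or, for 3 collagen genes, after their values were seen, 105 kept the call without each library in turn and 103 under each alternative run.

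Results that turned direction were not past the threshold in either case. For p53 targets the camera adjusted p was 0.957 with upper-quartile scaling, 0.894 with DESeq2 and 0.98 with no filter, and 0.833 to 0.962 without 1 library each. For WNT response it was 0.918 with DESeq2 and 0.885 to 0.972 without 1 library. For Sertoli targets it was 0.97 with DESeq2, 0.981 with no filter and 0.765 to 0.949 without 1 library, and for histones 0.918 and 0.77 with DESeq2 and no filter. Without the 2 libraries highest in interferon genes, a setting chosen after seeing the data, p53, WNT and Sertoli lists turned at 0.945, 0.775 and 0.749, CYP26B1 had a log2 change of 0.0364 and LIPE of 0.0296. Without 1 library each, CD14 ranged from -0.12 to 0.78 and COL2A1 from -0.37 to 1.05. The cause was not tested. CD14, with 35 and 48 counts in the 2 groups, showed no change detectable at this depth. COL2A1 turned without Ad-SOX9 replicate 1, the library in which it stood highest. The alternatives for normalized values were not run, because the table holds counts.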

Other observations

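The tests of interferon genes and of other glial genes were chosen after the result was seen, as was the setting without 2 libraries. Beyond SOX9, 2 of 5 measured SOX family genes rose, SOX13 1.97-fold and SOX4 1.93-fold (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.178), and SOX12 at a log2 change of -0.10 passed without Ad-SOX9 replicate 3. WNT response genes were divided, with 4 of 13 higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.938). FRZB, a secreted WNT inhibitor of joint cartilage, rose 8.44-fold to 3.91 ± 0.0885 CPM (SD, n = 3) and TNFRSF19 1.41-fold, while MYC and CCND1 were 1.54- and 1.32-fold lower. Of 18 immediate early genes 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.616). FOS rose 3.59-fold from 1.07 ± 0.461 to 3.79 ± 0.491 CPM, and DUSP5 and DUSP1, phosphatases of MAP kinases, were 2.20- and 1.37-fold lower. The median log2 change of this list was 0.01 although camera's direction was down.

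Among 24 genes of the unfolded protein response 3 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.134, 0.0133 by DESeq2 statistics and 0.0445 with no filter). The falls were led by CHAC1, which degrades glutathione, at 1.48-fold, and TRIB3 at 1.27-fold, both targets of the transcription factor ATF4. The chaperone gene HSP90B1 did not pass (log2 0.04, adjusted p = 0.379). Of 22 p53 targets 5 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.938), with TP53INP1 1.35-fold higher and GDF15 1.35-fold lower, and 3 rose without Ad-eGFP replicate 1 or 2, with RLE or upper-quartile scaling, by DESeq2, with no filter and with the replicate number as a block. SOX9 also acts in Sertoli cells, yet of 4 measured gonadal targets PTGDS alone passed, at 1.09-fold (1 higher adjusted over the list alone; camera adjusted p = 0.932), and not without Ad-eGFP replicate 1 or 3 or Ad-SOX9 replicate 1 or 2. Of 24 HOX genes 2 rose (1 higher adjusted over the list alone; camera adjusted p = 0.742), and the rise of HOXA9 (log2 0.40) was lost without any 1 of 5 libraries. Of 19 replication-dependent histone genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.742), and 1 rose without Ad-eGFP replicate 3 or any of the Ad-SOX9 replicates. Of 433 zinc finger genes with ZNF symbols 50 rose and 21 fell (34 and 11 adjusted over the list alone; camera adjusted p = 0.197), with ZNF267 1.80-fold and ZNF620 3.49-fold higher, and 13 fell without Ad-eGFP replicate 2. This excess of rises was not kept with the length and GC correction, where 33 rose and 33 fell and the median log2 change went from 0.0713 to 0.0276, or 27 and 25 with the block as well, and it was 74 and 12 with library size as the only scaling. Histone and zinc finger genes have close copies with which reads could be shared.

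The authors' deposited table has 29 of the 30 interferon genes marked as outliers and 1 called, against 10 of 30 cell cycle genes marked and 0 of 76 ribosomal protein genes. The median of the ribosomal protein genes, -0.21, lay below those of 10000 random lists of 76 genes matched on expression (median -0.04, lowest -0.12) and of 10000 matched on expression and transcript length (median -0.07, lowest -0.16), as a description of these libraries.

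The rise of interferon genes was set against 2 technical explanations. A single library does not account for it, since the median log2 change of the 30 genes was 0.834 without Ad-SOX9 replicate 2 and 1.37 without Ad-eGFP replicate 1, the lowest and highest of the 6 fits. A larger dose of SOX9 virus cannot be told apart from an effect of SOX9, because the level of virus in the groups was not analysed here. Within Ad-SOX9 the library with the most SOX9 reads (1919 CPM) and that with the fewest (1579 CPM) differed in the interferon mean by -0.013, too few libraries to decide. Innate sensing of virus, SOX9 itself or a difference between cultures may underlie the rise, and all stay open.

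The myelin genes PMP2 and MOBP rose together, and glial or Schwann cells in some cultures could bring them. Against this, the summed counts of 7 other glial genes of low level rose 1.85-fold (95% counting interval up to 2.72). These were S100B, SOX10, CDH19, ERBB3, NGFR, FOXD3 and GFAP. Their rise was far below those of PMP2 and MOBP, whose 95% counting intervals started at 211-fold and 80.1-fold. MBP, the abundant basic protein of myelin, was at 0.78-fold (0.621 to 0.978). Reads spilling over from paralogs are argued against by FABP3, FABP4 and FABP5, which together were at 0.854-fold (upper bound 0.966) and had 526 counts in Ad-eGFP, where PMP2 had 0. What raised the 2 genes stays open.

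Genes of low level were shifted upward in Ad-SOX9. Among the 2698 tested genes of lowest mean level (median 1.77 CPM), 373 rose and 99 fell, with a median log2 change of 0.12, against 538 and 968 among the 2698 of highest level, with a median of -0.04. Deeper sequencing is argued against, because after thinning each library to the same total Ad-SOX9 libraries still had on average 388 more genes detected (16668 to 16767 against 16298 to 16341), and a trend with transcript length and GC content left the median at 0.111 after correction. A uniform background of stray reads cannot be told apart, since olfactory receptor genes, which fibroblasts do not use, held 64 and 83 counts, a ratio of 1.13 (0.808 to 1.60) that spans the median fold of 1.08.

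Among the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes, 4709 and 286 at 1.5-fold, and the highest of the others by edgeR was 0 for both counts, with 117 to 293 genes at an unadjusted p under 0.05 against 5824. With 10 splits a share under 0.05 cannot be reached. Every other split also put Ad-SOX9 and Ad-eGFP libraries on the same side. The difference between the groups then counted as spread within a side, which keeps the counts of those splits low. Their counts therefore do not show how many genes would be called without a group difference, and no conclusion is drawn from the contrast.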
